A study of Mus musculus with 4 samples.

How the data were processed

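DNA methylation was measured by whole-genome bisulfite sequencing in 4 libraries from the testis of C57BL/6 mice. Bisulfite turns unmethylated cytosine into uracil, read as T, and leaves methylated cytosine as C, so that the share of C among the reads at a CpG gives its methylation level. Per the labels, the cells were THY1+ undifferentiated spermatogonia and KIT+ differentiated spermatogonia from mice 6 to 8 days old, and pachytene spermatocytes (4N) and round spermatids (1N) from mice 6 to 8 weeks old. Samples were grouped by the cell type in their labels, which gave 4 groups of 1 library each. An antibody is named in the labels for each of the spermatogonial samples and a ploidy for each of the others, so age and way of isolation changed together between the second and the third cell type. The libraries were made with a Pico Methyl-Seq kit, per the labels' protocols, in which adapters are added after bisulfite treatment.

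The authors deposited a table per library that lists CpGs with a strand, a coverage and the shares of C and T. Per the file headers, the coverage is a raw count of reads at a CpG. The deposited C and T values are a fraction of that coverage, rounded to 3 decimals. BSMAP 2.89 and the mouse build mm9 are named in the submitters' processing notes. The trimming, the removal of duplicate reads and the program that called methylation are not given in the sources used here. Methylated reads were recovered as coverage times the C fraction, and this product was whole within 0.00051 times the coverage, the rounding of the fractions, at every CpG where it was tested. The 379 to 479 CpGs per library with the most reads were not tested by this, since there the rounding spans a whole read. A CpG is marked as read on the plus strand, the minus strand or both, with the reads of both strands added.

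Between 17085481 and 18268580 CpGs were listed per library, out of 20928494 listed in any of the 4. Total reads at CpGs ranged from 85546923 to 98839440, with a median of 4 reads per CpG in each library. A single CpG at that depth has a coarse level, and comparisons therefore rest on windows, chromosomes and classes of CpGs. Intervals are exact (Clopper-Pearson) 95% binomial intervals. They cover counting error only, as do statements on a count of 0, since PCR reads without molecular identifiers are not independent molecules and a read pair can cover several CpGs.

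The genome-wide level was the share of methylated reads among all CpG reads of the 19 autosomes. CpGs with at least 5 reads were put into classes of at most 20%, at least 80%, and between. For CpG density, windows of 1 kb were classed by the number of CpGs listed in any library (1 to 5, 6 to 10, 11 to 20, 21 to 40, over 40). Levels of X and Y were set against the spread between the 19 autosomes, which is a spread over the genome and not over samples. Correlations were taken across 1 kb windows for the 6 pairs of libraries, without a p-value, because windows are not independent replicates.

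For changed windows, the methylated and unmethylated reads of a 1 kb window were compared between 2 libraries by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the windows tested. A window needed at least 4 covered CpGs and 20 reads in both libraries. It was called at an adjusted p under 0.05 and a difference of at least 20 percentage points. With 1 library per group there is no replicate check, and the test compares the libraries, not the cell types. A technical floor was measured by running the same test within a library, on alternating (odd against even) CpGs and on CpGs read on the plus strand only against those read on the minus strand only. Odd and even CpGs share sequenced molecules, whereas the strand sets do not share strands, so the second is the stricter floor, but it uses few windows with thin coverage. Both compare different CpGs of a window.

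The window test was tested on simulated data made at the depth of the KIT+ and pachytene libraries (1034895 windows, of which 200 were changed). With independent reads, 36.0% of 30-point and 81.5% of 50-point changes were recovered, with 2 false calls in the 30-point run. When 4 reads shared a call, 66.5% and 92.5% were recovered, and 5.6% of unchanged windows were called in the 30-point run. Changes were never called in the wrong direction. The Benjamini-Hochberg limit loosens as more windows pass. With only 200 changed windows it was stricter than in the data, so these recoveries are not those of the data. The false calls with shared reads loosened it, and the higher recovery there was not separated from this.

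The tests, thresholds, window sizes and most alternatives were fixed before the data were examined. Windows named in the text are those with the largest change, 5 per direction and comparison, with ties ordered by adjusted p. The longest runs of adjacent called windows, the 100 kb windows named by coordinates, the windows with extreme read pile-up and the mitochondrial CpGs were chosen after the data were seen. The fixed alternatives were other read minimums, differences and window sizes, thinning of reads, removal of CpGs above 5 times the median coverage (for the genome-wide level), subtraction of the median difference, a bound of 1 read per CpG strand, and CpGs covered in the libraries compared. After the data were seen, the coverage limit was also applied to CpG density, chromosomes and changed windows. A second way of removing pile-ups was then defined, with the values of the first already known: leaving out the 109 windows with at least 100 times the median window's reads in all 4 libraries, here called the piled-up windows. It was also combined with the CpGs covered in all 4 libraries. Both ways are given in the closing section. The strand floor was added after the data were seen as well.

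Coordinates are those of mm9. The gene table used here is of another build (GRCm38.p6), and coordinates were not carried between builds. Changed promoters, imprinted regions and the gene lists fixed beforehand (imprinted regions, spermatogonial, meiotic and spermatid genes, genome defence, DNA methylation machinery, pluripotency, developmental regulators, housekeeping genes, and markers of Sertoli, Leydig, peritubular, vessel and blood cells) were therefore not analysed here, and windows are named by position alone. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures matplotlib 3.10.9.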

Results

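The series profiled CpG methylation through mouse spermatogenesis in 4 cell types: THY1+ undifferentiated spermatogonia, the population that holds the spermatogonial stem cells, KIT+ differentiating spermatogonia, pachytene spermatocytes in meiotic prophase, and haploid round spermatids. Each cell type had 1 library, with no replicates. The THY1+, KIT+, pachytene and round spermatid libraries held 93314206, 86777773, 98839440 and 85546923 reads at CpGs, and 42.5%, 40.8%, 45.6% and 37.6% of their listed CpGs had at least 5 reads.

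The first question was how much of the genome's CpG methylation each cell type carried. THY1+ spermatogonia had the lowest level on autosomes, 67.6% (SD over 19 autosomes, 1.95), and KIT+ spermatogonia had 72.6% (SD 3.25). Pachytene spermatocytes and round spermatids were higher, at 76.4% (SD 3.13) and 76.0% (SD 4.97). Counting error was below these digits, with an interval from 67.638% to 67.658% in the THY1+ library. The order of the last pair depended on read pile-ups: without the 109 piled-up windows the levels were 67.3%, 74.5%, 78.2% and 79.2%, with SDs of 1.52, 1.06, 1.11 and 1.08. The gap between the last pair also depended on how reads were spread over windows of different CpG density. Within classes of CpG density, round spermatids then lay at most 0.106 points above pachytene spermatocytes. On CpGs with at least 5 reads in all 4 libraries the order turned, with 68.2%, 65.2%, 67.7% and 63.7%, and without the piled-up windows these CpGs had 66.62%, 72.53%, 75.02% and 75.35%. No library was replicated, so these differences have no error between animals or preparations.

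Highly methylated CpGs became more frequent along the same order of cell types. Among CpGs with at least 5 reads, 52.7% were at least 80% methylated in THY1+ spermatogonia, 64.8% in KIT+ spermatogonia, 72.0% in pachytene spermatocytes and 73.1% in round spermatids. The share between the limits of 20% and 80% was 29.0% in THY1+ spermatogonia and fell through 19.4% to 13.2% and 13.1%. CpGs of at most 20% made up 18.3%, 15.9%, 14.9% and 13.8%. In 870773 windows of 1 kb covered in all 4 libraries, the median level was 77.4% in THY1+ spermatogonia (quartiles 62.1% and 87.1%), 89.2% in KIT+ spermatogonia (78.5% and 94.8%), 93.9% in pachytene spermatocytes (84.0% and 97.6%) and 94.1% in round spermatids (84.0% and 97.8%). Windows with intermediate levels, above 20% and under 80%, made up 50.3% in THY1+ spermatogonia and 14.0% in each of the adult cell types. Windows at 10% or less made up 3.44% in THY1+ spermatogonia, 4.91% in KIT+ spermatogonia, 5.44% in pachytene spermatocytes and 5.29% in round spermatids. The fall in CpGs of at most 20% was thus not matched by a fall in unmethylated windows.

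**Figure D1:**
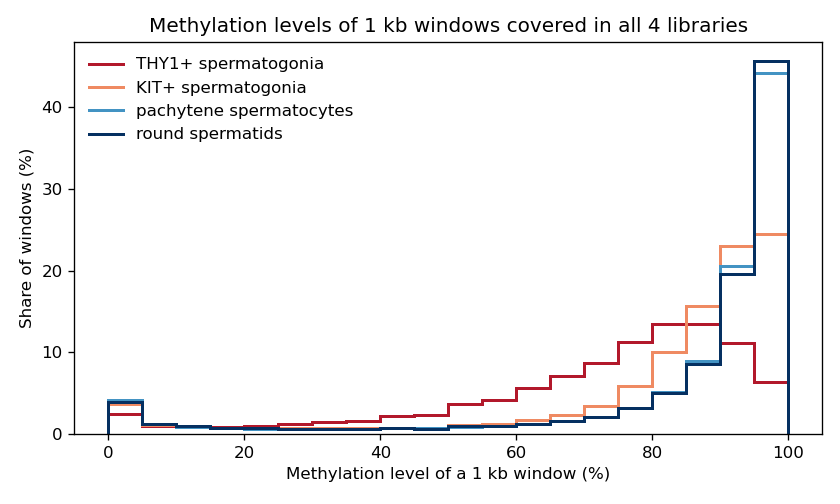
Share of 1 kb windows (vertical axis, %) by methylation level in bins of 5 points (horizontal axis, %), for the 870773 windows covered in all 4 libraries, with 1 line per library. The pachytene and round spermatid lines nearly coincide, with 44.2% and 45.7% of windows in the highest bin, where the THY1+ library has 6.42%.

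Pachytene spermatocytes and round spermatids were the most similar pair of cell types, with a Pearson r of 0.949 across the 870773 windows (Spearman's rho 0.641) and a median absolute difference of 3.83 points. KIT+ spermatogonia correlated with these at 0.921 and 0.919 (rho 0.585 and 0.583). THY1+ spermatogonia stood apart from the other 3 cell types, at 0.527 with KIT+ spermatogonia, 0.504 with pachytene spermatocytes and 0.502 with round spermatids (rho 0.295, 0.237 and 0.235). Their median absolute difference from KIT+ spermatogonia was 12.8 points. Windows are not independent replicates, and no p-value was computed.

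The mean level rose in CpG-poor sequence, whereas the mean of the densest windows was nearly the same in the 4 libraries. In windows with 1 to 5 CpGs the level was 73.9% in THY1+ spermatogonia, 85.6% in KIT+ spermatogonia, 89.8% in pachytene spermatocytes and 89.9% in round spermatids. In windows with 6 to 10 CpGs it was 74.4%, 85.7%, 89.4% and 89.3%, and with 11 to 20 CpGs it was 72.8%, 79.1%, 82.5% and 79.4%. Windows with more than 40 CpGs, the density of CpG islands, stood at 18.2%, 18.9%, 18.7% and 18.6%. The class of 21 to 40 CpGs had 66.1%, 63.5%, 64.7% and 62.6%. Piled-up windows weighed on the denser classes: without them the class of 11 to 20 CpGs had 72.3%, 83.1%, 86.0% and 86.0%. In the class of 21 to 40 CpGs the difference between round spermatids and THY1+ spermatogonia went from -3.45 to 0.674 points without them, so its direction was not settled. This mean also hides changes in both directions, since from THY1+ to KIT+ spermatogonia 13.1% of the windows with 21 to 40 CpGs gained and 17.1% lost. Over 40 CpGs, 0.369% gained and 5.4% lost.

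**Figure D2:**
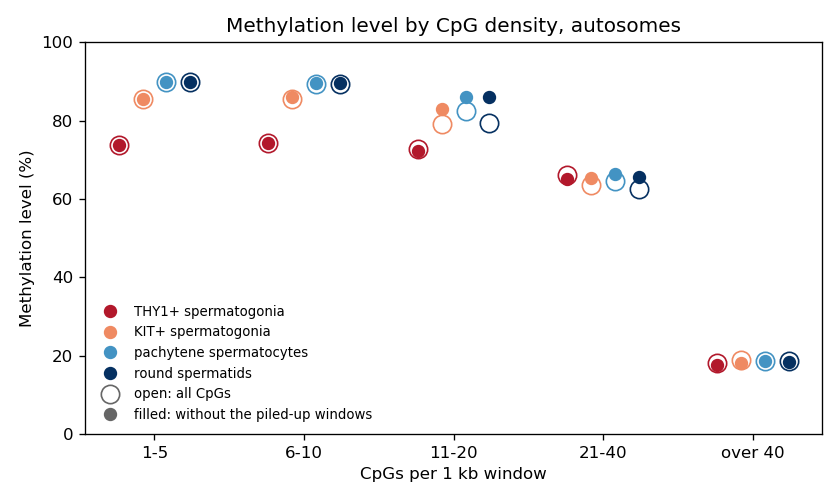
Methylation level of autosomes (vertical axis, %) by the number of CpGs in a 1 kb window (horizontal axis), 1 point per library, with open circles for all CpGs and filled points without the 109 piled-up windows. Libraries part in the classes up to 20 CpGs, where THY1+ spermatogonia lie lowest, and meet near 18% in windows with more than 40 CpGs.

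The X chromosome, silenced during meiosis together with Y, was compared with the autosomes in each cell type. In THY1+ spermatogonia X was more methylated than the autosome mean, at 70.3% against 67.4%. In KIT+ spermatogonia it was less methylated, at 70.9% against 74.6%, and so it was in pachytene spermatocytes (73.1% against 78.2%) and round spermatids (73.1% against 79.2%). These values leave out the piled-up windows. X then lay 1.9, -3.5, -4.59 and -5.7 SDs of the 19 autosomes from their mean. With all CpGs, X minus the autosome mean was 2.81, -2.32, -3.74 and -4.12 points. Without the piled-up windows, X rose by 0.583 points from THY1+ to KIT+ spermatogonia and the 19 autosomes by 5.55 to 9.02 points. With all CpGs X changed by 0.587 points and the autosomes by -5.05 to 8.92, so that X then lay within their range. From KIT+ spermatogonia to pachytene spermatocytes X rose by 2.23 points and the autosomes by 3.3 to 3.81 without the piled-up windows, and by 2.22 and 3.28 to 4.43 with all CpGs. Among CpGs with at least 5 reads in all 4 libraries X minus the autosome mean was 3.305, 1.44, -2.02 and -3.03 points, with the other sign in KIT+ spermatogonia and a smaller gap in the adult cell types. The Y chromosome, with few CpGs in these tables, stood at 61.1%, 57.1%, 54.0% and 52.5% without the piled-up windows and at 60.4%, 54.1%, 50.7% and 49.5% with all CpGs. Its change from KIT+ spermatogonia to pachytene spermatocytes was -3.12 points without the piled-up windows but 1.19 points without CpGs above 5 times the median coverage, so its direction was not settled.

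**Figure D3:**
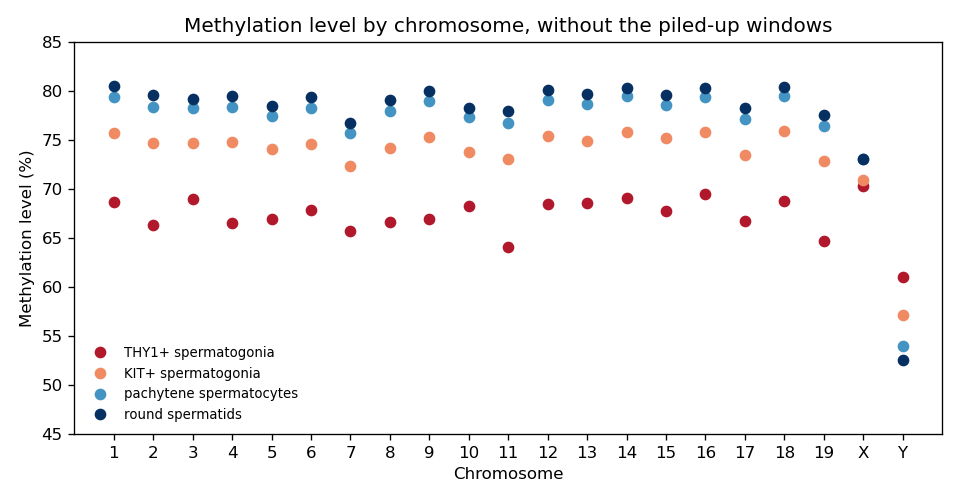
Methylation level (vertical axis, %, from 45) of the 19 autosomes, X and Y (horizontal axis) without the 109 piled-up windows, 1 point per library. On X the 4 libraries lie between 70.3% and 73.1%, a narrower range than on the autosomes, where the means run from 67.4% to 79.2%.

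The step from THY1+ to KIT+ spermatogonia, labelled as undifferentiated and differentiated, held most of the change between libraries. With 1 library per cell type, a change of cell state could not be told apart from other cells or a wrong label in the THY1+ library. Of 998507 windows of 1 kb tested, 236120 (23.6%) were higher in KIT+ spermatogonia and 60521 (6.06%) were lower, with a median difference of 8.09 points. Gains were most frequently called in windows with 11 to 20 CpGs (26.9%) and losses in windows with 21 to 40 CpGs (17.1%). Calls also depend on the reads per window, which were not matched between classes. Without the piled-up windows the mean level rose by 11.7 points in windows with 1 to 5 CpGs and by 10.8 points in those with 11 to 20. On X the balance was the opposite of that on autosomes: 7.68% of its windows gained and 13.0% lost, against 21.1% to 27.2% and 4.5% to 7.58% over the autosomes. The gained windows had a median of 57.1% in THY1+ spermatogonia and 93.5% in KIT+ spermatogonia, and then 95.8% and 96.0% in pachytene spermatocytes and round spermatids. The lost windows went from 77.1% to 26.5%, and had 26.0% and 26.4% in the adult cell types.

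Windows that gained most went from no methylated read to complete methylation. They start at 31979001 on chromosome 12, 139060001 on chromosome 3, 140494001 on chromosome 2, 115432001 on chromosome 13 and 16527001 on chromosome 16. The first had 0% in THY1+ spermatogonia (0 of 43 reads, upper bound 8.22%) and 100% in KIT+ spermatogonia (62 reads, lower bound 94.2%), with an adjusted p of 4.4e-28 by Fisher's exact test. It kept 100% in pachytene spermatocytes (74 reads) and round spermatids (48 reads). The windows that lost most start at 113173001 and 28617001 on chromosome 14, 114306001 on chromosome 13, 133462001 on X and 45616001 on chromosome 2. The X window, with 37 CpGs, had 100% in THY1+ spermatogonia (20 reads) and 0% in KIT+ spermatogonia (114 reads), pachytene spermatocytes (61 reads) and round spermatids (70 reads). Reads of a window are summed over its CpGs, so 1 molecule can count at several CpGs. The 20 reads in THY1+ spermatogonia were the minimum for a test. Changes also spanned longer regions. On chromosome 15 an 18 kb run from 85507001 to 85525000 rose from 44.1% to 87.7% (1601 and 1471 reads), and a 15 kb run on chromosome 4 from 132597001 to 132612000 rose from 29.7% to 86.0%. On chromosome 6 a 28 kb run from 114515001 to 114543000 fell from 52.3% to 16.2% (7552 and 5756 reads) and stood at 13.7% and 14.7% in the adult cell types. Within single libraries the strand floor was 7.18% and 7.34% in THY1+ spermatogonia and 3.94% and 3.66% in KIT+ spermatogonia, against 14.1% gains and 8.58% losses between these libraries on plus-strand CpGs. Odd against even CpGs gave 1.22% and 1.23% in THY1+ spermatogonia and 0.0686% and 0.0708% in KIT+ spermatogonia, against 21% gains and 7.3% losses between the libraries on odd CpGs. The gains thus lie above both floors, and the losses above that of odd and even CpGs but close to the strand floor of the THY1+ library. With at most 1 read counted per CpG strand, 3.82% of windows gained and 2.19% lost.

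KIT+ spermatogonia and pachytene spermatocytes, before and within meiosis, differed by a small shift that was seen on every autosome. The autosomes rose by 3.3 to 3.81 points without the piled-up windows, and the median window rose by 2.72 points. Within classes of CpG density the rise without these windows ran from 4.18 points in the sparsest to 0.538 points in the densest. Pooled levels of autosomes also depend on how reads were spread over these classes. Called windows were few: 26911 of 1034879 (2.6%) were higher in pachytene spermatocytes and 9588 (0.926%) were lower. In the gained windows the median was 68.0% in KIT+ spermatogonia and 96.9% in pachytene spermatocytes, and 93.0% in round spermatids. The last is close to the round spermatid median of 94.1% over all windows covered in the 4 libraries. It thus cannot tell a true gain from a KIT+ level that was measured too low. The lost windows had 65.9%, 29.1% and 42.7%. The longest run of gained windows, 7 kb on chromosome 8 from 124345001 to 124352000, had 77.4% in THY1+ spermatogonia (2613 reads), 18.9% in KIT+ spermatogonia (2692 reads), 58.5% in pachytene spermatocytes (1913 reads) and 54.8% in round spermatids (1837 reads). The largest single gains start at 51334001 on chromosome 10, 117270001 on chromosome 13, 90456001 on chromosome 5, 95069001 on chromosome 6 and 1398001 on Y. The chromosome 10 window went from 4.17% (24 reads) to 100% (25 reads), with 68.8% in round spermatids (16 reads). The largest single losses start at 127831001 and 50513001 on chromosome 3, 87463001 on chromosome 17, 98704001 on chromosome 10 and 100952001 on chromosome 2. The last went from 86.7% (60 reads) to 5.88% (34 reads), with 0% in round spermatids (45 reads). Window calls in this step lay above one technical floor and below the other. On odd CpGs 1.23% gained and 0.565% lost between these libraries, against at most 0.102% between odd and even CpGs of either library. On plus-strand CpGs 2.23% gained and 1.54% lost, fewer than the 3.94% and 3.66% between strands of the KIT+ library and the 3.18% and 3.23% of the pachytene library. With at most 1 read counted per CpG strand, 80 windows gained and 70 lost.

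Pachytene spermatocytes and round spermatids, on either side of the meiotic divisions, had nearly the same methylation. The median window differed by 0 points, and 4839 (0.449%) of 1078085 windows were higher in round spermatids while 4680 (0.434%) were lower. Without the piled-up windows the pooled level of the autosomes rose by 0.806 to 1.23 points, and X changed by -0.0191 points. With all CpGs the autosomes changed by -5.6 to 1.83 points and X by -0.0228 points. Without the piled-up windows the classes of CpG density changed by 0.106, 0.0768, 0.0656, -0.658 and -0.143 points, from sparse to dense. None rose as much as the pooled level, so that rise came with a different share of reads per class. In the windows called higher, the medians were 39.0% in pachytene spermatocytes and 76.9% in round spermatids, with KIT+ spermatogonia between them at 56.7%. In those called lower, the medians were 78.8% and 41.7%, with KIT+ spermatogonia at 62.7%. The largest gains start at 10248001 on chromosome 11, 156039001 on X, 20752001 and 60081001 on chromosome 1 and 37894001 on chromosome 16. The largest losses start at 31551001 on chromosome 2, 34494001 and 41445001 on chromosome 6, 91337001 on chromosome 8 and 53982001 on chromosome 4. The chromosome 8 window, which had 22 CpGs, was the best covered of these, with 88.0% in pachytene spermatocytes (83 reads) and 12.9% in round spermatids (124 reads; adjusted p of 3.4e-23 by Fisher's exact test). On odd CpGs 0.203% gained and 0.187% lost between these libraries, against at most 0.102% between odd and even CpGs of either. On plus-strand CpGs the calls were below the floor, with 1.06% and 1.02% between the libraries against 2.6% and 2.56% between the strands of the round spermatid library. With at most 1 read counted per CpG strand, 117 windows gained and 33 lost.

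Over the whole span, from THY1+ spermatogonia to round spermatids, 316203 of 1040542 windows (30.4%) were higher in round spermatids and 60277 (5.79%) were lower, with a median difference of 11.5 points. Gains made up 84.0% of the calls, and 71.9% after the median difference was subtracted for the 20-point limit. Fisher's test was not shifted with it, which favours gains, so the 71.9% does not give the balance around the median. In the gained windows KIT+ spermatogonia already had a median of 91.1%, between 61.2% in THY1+ spermatogonia and 96.9% in round spermatids. In the lost windows they had 27.9%, between 75.4% and 21.3%. The longest gained run, 20 kb on chromosome 5 from 124608001 to 124628000, went from 49.6% to 94.4%, with 90.1% in KIT+ spermatogonia. An 18 kb run on chromosome 15 from 27707001 to 27725000 went from 36.1% to 95.6%, with 95.1% in KIT+ spermatogonia. The largest single gains start at 29809001 on chromosome 10, 51899001 on chromosome 17, 164619001 on chromosome 2, 139060001 on chromosome 3 and 82787001 on chromosome 7. Of these, the chromosome 17 window had 0% in THY1+ spermatogonia (110 reads, upper bound 3.3%), 66.7% in KIT+ spermatogonia (33 reads), 88.3% in pachytene spermatocytes (77 reads) and 100% in round spermatids (31 reads). The largest single losses start at 120795001 on chromosome 14, 11015001 on chromosome 3, 66015001 and 117478001 on X and 69926001 on chromosome 7. The chromosome 14 window fell from 100% (39 reads) through 13.1% (99 reads) and 5.68% (88 reads) to 0% (147 reads; adjusted p of 2.2e-38 by Fisher's exact test). On plus-strand CpGs 15.2% of windows gained and 8.19% lost, against at most 7.34% between the strands of a library, and on odd CpGs 26.8% gained and 7.39% lost, against at most 1.23% between odd and even CpGs. With at most 1 read counted per CpG strand, 7.37% gained and 2.7% lost.

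**Figure D4:**
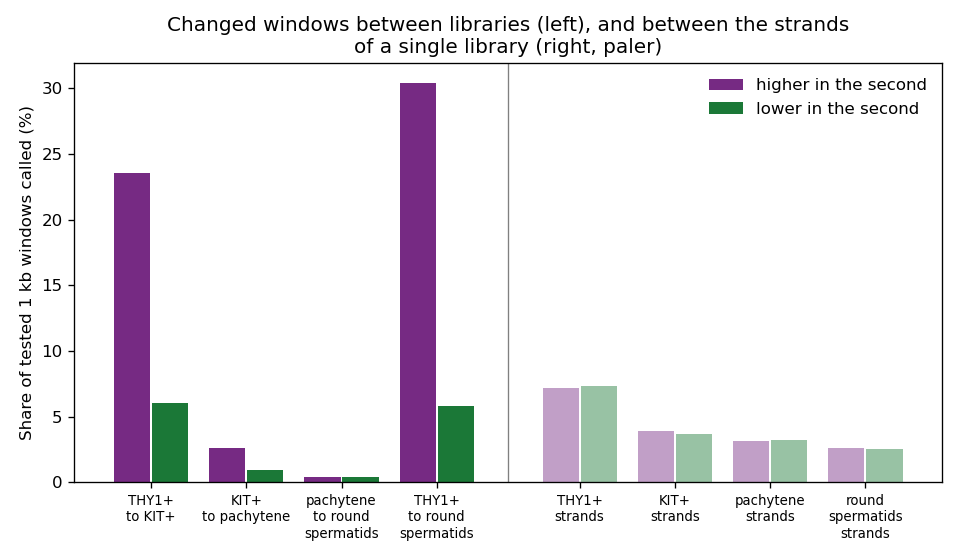
Share of tested 1 kb windows called higher (purple) or lower (green) in the second library (vertical axis, %), for the 4 comparisons on the left, and on the right, paler, for plus-strand-only against minus-strand-only CpGs within each library. The pachytene to round spermatid bars, 0.449% and 0.434%, and the KIT+ to pachytene bars, 2.6% and 0.926%, are lower than the strand bars of the libraries they compare. The loss bars of THY1+ to KIT+, 6.06%, and of THY1+ to round spermatid, 5.79%, are lower than the THY1+ strand bars, 7.18% and 7.34%. The strand bars rest on 14251 to 22186 windows per library.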

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

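The readings of mitochondrial CpGs were chosen for a look only after the data had been seen. They stand outside the comparisons of nuclear DNA, and no control samples were in the series. At 287 CpGs of the mitochondrial genome, C made up 5.0% of reads in THY1+ spermatogonia (95% interval 4.87% to 5.14%, 98477 reads). The share was 5.72% in KIT+ spermatogonia (5.49% to 5.95%), 3.56% in pachytene spermatocytes (3.37% to 3.76%) and 5.38% in round spermatids (5.03% to 5.74%). The order of the libraries did not follow the order of the cell types. Depth per mitochondrial CpG over that of autosomes was 79.5 in THY1+ spermatogonia, 33.4 in KIT+ spermatogonia, 26.4 in pachytene spermatocytes and 14.2 in round spermatids. No explanation of these shares was tested, neither a technical one (unconverted cytosines, nuclear copies of mitochondrial sequence) nor a biological one.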

How the results depend on the processing

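The alternatives chosen after the data were seen were removal of the 109 piled-up windows (alone or with the CpGs shared by all libraries) and, except for the genome-wide level, removal of CpGs above 5 times the median coverage; the latter was run first. Unless stated, values are in the order THY1+, KIT+, pachytene and round spermatid, the cause of a change was not tested, and a setting not named gave a value within counting error or, for window calls, within 1.5 times the reported share. Of the steps between neighbouring cell types by CpG density, 28 values moved beyond counting error without a change of direction, and only a few of them are given below. The order of the first 3 cell types in genome-wide level held under every alternative except that of CpGs shared by all libraries with piled-up windows kept, while round spermatids passed pachytene spermatocytes in most of them. Depth limits single CpGs, with a median of 4 reads. At the depth of the KIT+ and pachytene libraries the window test found 36.0% of simulated 30-point changes. Only 200 windows were changed in that simulation, which made the adjusted limit stricter than in the data, so this share was not set by depth alone. No paired analysis was possible because each cell type had 1 library, which also rules out leaving out replicates or regrouping samples. The effective count corrected for variants was not run, since the tables used here have no such column, and neither were alternatives for promoters, imprinted regions and gene lists, which were not analysed here.

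Genome-wide levels averaged over CpGs with at least 1 read were 68.5%, 76.0%, 79.4% and 79.8%. With at least 3 reads they were 67.8%, 75.2%, 78.7% and 79.5%, with at least 5 reads 67.0%, 74.2%, 78.0% and 79.2%, and with at least 10 reads 65.3%, 72.1%, 76.6% and 78.5%. Thinning to 5 reads per CpG gave 67.0%, 74.2%, 78.0% and 79.1%, and removal of CpGs above 5 times the median coverage 67.4%, 74.8%, 78.5% and 79.5%. Without the piled-up windows they were 67.3%, 74.5%, 78.2% and 79.2%. Only CpGs with at least 5 reads in all 4 libraries, 1548766 CpGs, gave 68.2%, 65.2%, 67.7% and 63.7%, so that THY1+ spermatogonia were then highest. Without the piled-up windows the same CpGs gave 66.62%, 72.53%, 75.02% and 75.35%, so the turn rested on those windows. X minus the autosome mean was 3.305, 1.44, -2.02 and -3.03 points on the shared CpGs, 2.885, -3.697, -5.086 and -6.136 without the piled-up windows and 3.5, -3.52, -4.28 and -5.24 with the coverage limit, in place of 2.81, -2.32, -3.74 and -4.12. Shares of CpGs of at most 20% became 18.9%, 17.9%, 15.9% and 13.5% with at least 10 reads, 21.3%, 17.2%, 15.9% and 14.8% after thinning to 5 reads, and 14.2%, 14.0%, 13.3% and 12.1% with a limit of 10%. Shares of at least 80% became 50.7%, 64.9%, 71.6% and 72.8% with at least 10 reads, 58.5%, 69.5%, 75.1% and 76.1% after thinning, and 39.8%, 52.0%, 61.8% and 62.7% with a limit of 90%.

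By CpG density, the change from THY1+ spermatogonia to round spermatids is given for the 5 classes from sparse to dense. It was 16.0, 14.9, 6.63, -3.45 and 0.454 points as reported. With windows of 500 bases it was 16.6, 14.9, 11.6, -6.18 and 1.5 points. Without the piled-up windows it was 16.0, 15.2, 13.7, 0.674 and 0.738 points, and without CpGs above 5 times the median coverage 16.3, 15.6, 13.9, 0.732 and 0.0964 points, so the class of 21 to 40 CpGs turned under both removals. From pachytene spermatocytes to round spermatids, the classes of 6 to 10 and 11 to 20 CpGs went from -0.068 and -3.1 points to 0.0768 and 0.0656 without the piled-up windows, and to 0.0753 and 0.0829 with the coverage limit. From THY1+ to KIT+ spermatogonia, the class of 21 to 40 CpGs went from -2.54 to 0.264 points without the piled-up windows but -0.133 with the coverage limit. Over 40 CpGs, the 3 steps were 0.725, -0.204 and -0.0662 points as reported. There the step from THY1+ to KIT+ spermatogonia became -1.68 with the coverage limit. The step from KIT+ spermatogonia to pachytene spermatocytes became 0.225 with 500-base windows, 0.538 without the piled-up windows and 0.356 with the coverage limit. The step to round spermatids became 0.0458 with 500-base windows and 1.42 with the coverage limit.

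Correlations, in the order THY1+ with KIT+, pachytene and round spermatid, KIT+ with pachytene and round spermatid, and the last pair, were 0.567, 0.552, 0.547, 0.911, 0.907 and 0.938 in 5 kb windows and 0.653, 0.629, 0.626, 0.961, 0.959 and 0.974 with at least 40 reads. Shares of changed windows are in the order of the 3 steps and the whole span. With at most 1 read per CpG strand, gains were 3.82%, 0.00773%, 0.0109% and 7.37% and losses 2.19%, 0.00676%, 0.00306% and 2.7%. This setting tests far fewer reads and also removes reads that may share a call. Which of these lowered the shares was not tested. In 100 kb windows gains were 1.77%, 0.0234%, 0.0117% and 9.41% and losses 0.292%, 0.00389%, 0% and 0.389%. A limit of 30 points gave gains of 15.2%, 1.05%, 0.257% and 19.05%, and losses of 0.492% and 0.249% in the steps to pachytene spermatocytes and to round spermatids. A limit of 10 points gave 4.53% gains from KIT+ spermatogonia to pachytene spermatocytes, where 5 kb windows gave 0.569% losses. At least 40 reads gave 0.751% gains and 0.71% losses from pachytene spermatocytes to round spermatids. Subtracting the median difference left 17.5% gains over the whole span.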

Other observations

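The tests in this part were chosen after the result they bear on had been seen, except the depth test for the THY1+ library and the 3 tests on the X chromosome, whose read weights were added afterwards. The X tests leave out CpGs above 5 times the median coverage.

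Some of the windows with extreme coverage changed in a way of their own. In all 4 libraries 109 windows held at least 100 times the reads of the median window, 42 of them on chromosome 9 and 13 on chromosome 2. Their median level was 72.2% in THY1+ spermatogonia, 37.0% in KIT+ spermatogonia, 33.6% in pachytene spermatocytes and 33.1% in round spermatids, opposite to the genome. From THY1+ to KIT+ spermatogonia 77 of the 109 were lower. The first 39 kb listed on chromosome 9, from 3000001 to 3039000, went from 74.7% to 39.8%, 36.3% and 36.6%, and a window on chromosome 2 that starts at 98507001 went from 77.8% (2130421 reads) to 41.1%, 38.2% and 38.2%. A CpG-dense cluster on chromosome 17 differed from these. Its window that starts at 39982001, with 124 CpGs, had 18.4% in THY1+ spermatogonia, 21.2% in KIT+ spermatogonia, 4.38% in pachytene spermatocytes and 5.78% in round spermatids, lower in the adult cell types than in the spermatogonia. Read pile-ups of this size can add up many genomic copies, so a level here is an average over copies.

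Over 100 kb windows the change was broad and shallow. From THY1+ to KIT+ spermatogonia 81.5% of 25683 windows were higher in KIT+ spermatogonia, with a median difference of 6.67 points, but 455 were called as gains and 75 as losses. From KIT+ spermatogonia to pachytene spermatocytes 89.4% were higher in the latter, with a median difference of 3.49 points, and 6 were called as gains and 1 as a loss. From 74000001 to 74100000 on chromosome 1 the level was 53.7% in THY1+ spermatogonia, 87.6% in KIT+ spermatogonia, 92.5% in pachytene spermatocytes and 92.4% in round spermatids. From 57600001 to 57700000 on chromosome 10 it was 76.9%, 30.2%, 26.4% and 26.6%. This stretch holds a piled-up 1 kb window that starts at 57687001, with 80.7%, 11.3%, 3.37% and 4.11%. In THY1+ spermatogonia that window had 4148 of the 18289 reads, and the level without it was not computed.

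The THY1+ library stood apart from the other 3. Depth was argued against by the totals, since its 93314206 reads at CpGs lay within the range of the others, 85546923 to 98839440. With all libraries thinned to the smallest total its highest correlation was 0.534, against 0.922 or more among the others. With totals this close, thinning could change little, so it adds little to this. Incomplete conversion was argued against for the 23.6% of windows lower in THY1+ than in KIT+ spermatogonia, since unconverted cytosines can only raise a level. That THY1+ levels were mostly lower was known when this test was chosen, and the 6.06% of windows higher in THY1+ are not covered. The mitochondrial C share of THY1+ minus the highest of the others was -0.71 points. That bears on conversion only if mitochondrial DNA is taken as unmethylated and its nuclear copies are set aside. A minority of other cells mixed in may still contribute, and the window counts do not decide it. In 5 kb windows at 90% or more in the other 3 libraries, 67 of 136212 were at 30% or less in THY1+ spermatogonia, and of those at 10% or less in the others 11 of 2390 were at 70% or more, 78 in all. In 1 kb windows, with the stricter limits of 95% and 5% for the others, it was 1820 of 98051 and 763 of 22627. A minority would not take the true level of a window that far, but how far a measured level strays from the true one was not known without replicates or counts of molecules. No bound on the counts was set before related values were seen. The median THY1+ level was 77.8% in 5 kb windows where the others were at 90% or more. A library made mostly of other cells, or a wrong label, could not be told apart from a true undifferentiated state either, because no somatic library was at hand. Of 1 kb windows at 5% or less in the other 3, 65.3% were at 5% or less in THY1+. That fell short of the 95% set as the mark against these causes. In windows at 95% or more in the other 3, the median THY1+ level was 82.0%. A true difference in cell state can give such values too, and the difference that the design names stays untested.

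KIT+ levels lay between those of THY1+ spermatogonia and the adult cell types. More complete conversion in the KIT+ library was argued against by its mitochondrial C share, 2.2 points above that of pachytene spermatocytes. This holds only if mitochondrial DNA is taken as unmethylated and its nuclear copies are set aside. Cells with a THY1+-like methylome in the KIT+ library may be the cause, in whole or in part. KIT+ minus pachytene was -3.08 points (SD over autosomes 0.088) over all windows. It was -3.25 points (SD 0.23) in windows at 95% or more in both THY1+ spermatogonia and round spermatids, where a mixture alone predicts a smaller gap. The windows at 95% or more were picked by their measured THY1+ level, so the true level there can be lower, and the value does not decide. KIT+ minus pachytene rose with THY1+ minus round spermatid at a slope of 0.0804, but a gradual change between cell states predicts the same slope, and these cannot be told apart. The same fit gave KIT+ minus pachytene as -2.09 points (SD over autosomes 0.091) where THY1+ equalled round spermatid. A mixture alone predicts no difference there, but error in the measured THY1+ levels can give one, and its size was not measured. Age, 6 to 8 days against 6 to 8 weeks, changed at the same step and stays open.

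X rose less than autosomes from THY1+ to KIT+ spermatogonia, by 0.289 points against 5.77 to 9.12 points on the autosomes over the CpGs used here. With no CpG left out, X changed by 0.587 points and the autosomes by -5.05 to 8.92, so X then did not lie below every autosome. The tests used windows of 1 kb with at least 20 reads in both libraries. In the 14291 such windows of X the mean fell, with a change of -3.87 points against 7.31 to 11.9 points on the autosomes, and -4.82 points with windows weighted by reads. What is said of causes thus holds for these windows. Matching on CpG density and starting level did not remove the gap. X still lay -10.8 points from the autosomes (SD 0.97), or -7.55 points with read weights (SD 1.1). Windows were matched by their measured THY1+ level, which also enters the change, and X had lower depth than the autosomes, which were not thinned here. Error in that level can thus add to the gap by an amount not measured, so the starting level stays open. The lower depth of X, taken alone, was argued against, since the lowest autosome thinned to that depth changed by 5.46 points. Whatever sets the THY1+ library apart may account for all of it. X also lagged from KIT+ spermatogonia to round spermatids, by -1.45 points (SD over autosomes 0.084), but that is another step, and a lag there leaves the source of the first step open although it had been set beforehand as evidence against this source. A difference of X between the cell states and a property of the THY1+ library cannot be told apart with 1 library per cell type.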
